A study of Homo sapiens with 10 samples.

How the data were processed

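RNA sequencing was carried out on 2 human pluripotent stem cell lines, the embryonic stem cell (ESC) line KhES-3 and the induced pluripotent stem cell (iPSC) line 201B7. Cells of each line were kept without feeder cells and exposed for 48 h to 0.1% dimethyl sulfoxide (DMSO), to 10 or 30 nM bisphenol A, or to 0.1 or 1 µM thalidomide. A DMSO percentage was given for the DMSO libraries only, so whether treated cells also received DMSO is unknown here. One library was deposited per line and treatment, 10 libraries in all, so that no line and treatment had a replicate. The labels number the samples of each line as a separate experiment series, so that line and series cannot be told apart.

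The deposited values were FPKM (fragment counts scaled to transcript length and library size), computed by the authors, with 1 value per gene symbol. The labels name HISAT2 2.1.0, Cufflinks and Cuffdiff and the genome build hg19, and state neither versions of Cufflinks and Cuffdiff nor the order of the steps. Each file held the same 26260 symbols. Genes of X inactivation and Y-linked genes (99 symbols) were left out of every table, which left 26161 symbols, of which 5825 were at 0 in every library. No counts were used here, so the number of fragments behind each value is unknown and no counting interval was computed. The FPKM of a library summed to between 504383 and 545830. A relative depth was read from the steps between the lowest values, those up to 0.15 FPKM, with the KhES-3 DMSO library set at 1. The step shared with that library held between 20.6% and 33.8% of the low genes compared, so the relative depth is approximate.

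Values were used as log2(FPKM + 1), so that log2 and fold changes are those of FPKM + 1 and are smaller than those of FPKM at low values. Genes with an FPKM of at least 1 in at least 2 libraries were tested, without 20 symbols of short RNAs, which left 13358 genes. Models were fitted to all 10 libraries with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05. The compound model held cell line and compound (6 residual degrees of freedom) and gave bisphenol A against DMSO, thalidomide against DMSO, and bisphenol A against thalidomide. The treatment model held cell line and the 5 treatments (4 residual degrees of freedom) and gave each dose against DMSO, the doses of a compound against each other, and 201B7 against KhES-3. The interaction model held line, compound and their product (4 residual degrees of freedom) and gave the line difference in the response to each compound. These made 12 comparisons. The spread came from the doses of a compound and from the lines, and a DMSO library, single in its line, was assumed to vary like the others. Within a line, treated libraries were set against the DMSO library of that line as values with no p. The same code was tested on simulated data with known changes.

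Gene lists (35, of which 32 had at least 5 tested members) were compared with all other genes by camera in limma with a preset inter-gene correlation of 0.01, adjusted over the 32 lists, and again with an estimated correlation. Named genes were, per comparison of a compound with DMSO, of the compounds and of the lines, the 10 called genes with the largest log2 change in each direction and a mean FPKM of at least 2. Where fewer than 5 of a direction passed, genes of smallest p with the same sign in both lines and at both doses filled it up to 5, given as values. Per list, called members and up to 4 members of smallest p could be named, and all members of the list of direct targets. For each line and compound, the 5 genes per direction with the largest smaller-of-both-doses difference could be named, and for each interaction the 5 genes of smallest p. Where a list had many called members, examples are given. Member counts are of tested members, and several lists of lineage markers had most of their members below the filter. Pseudoautosomal genes among these are not named.

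The groups, comparisons, gene lists, naming rule and first set of alternatives were chosen before the data were examined. The alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, quantile normalization, no intensity trend, no cell line term (no treatment term for the line comparison), leaving out each library in turn, other settings of the list test, and median-ratio scaling within lines. Chosen after the data were seen were the removal of a smooth trend with transcript length and GC content from each library within each line, and leaving out the genes of the major histocompatibility region. Lengths, GC content and gene neighbours came from GENCODE 29 on GRCh38, matched by symbol for 12689 of the 13358 genes, and positions in it served only to choose the neighbours of a gene and the genes of the major histocompatibility region. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.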

Results

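The series holds 10 RNA sequencing libraries of human pluripotent stem cells, 5 of the ESC line KhES-3 and 5 of the iPSC line 201B7. Each line has 1 DMSO library, 2 of bisphenol A and 2 of thalidomide. Between 12551 and 12791 genes reached 1 FPKM in a library. The relative depth was 0.812 to 1.04 in KhES-3 and 1.14 to 2.095 in 201B7, where the 30 nM bisphenol A library had the lowest value. Log2 values of libraries of the same line correlated across genes at 0.985 to 0.996, and those of different lines at 0.957 to 0.972. Genes are not independent replicates. There was no replicate of any line and treatment, and errors are standard errors (SE) of the limma model over all 10 libraries unless named as SD.

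The comparison of thalidomide with DMSO asked which genes changed after exposure to a teratogen that binds cereblon, the substrate receptor of a ubiquitin ligase. NPFFR2, a neuropeptide FF receptor, rose by 1.83 on the log2 scale (SE 0.22, adjusted p = 0.00153). NTS, the neuropeptide neurotensin, rose by 1.61 (SE 0.20, adjusted p = 0.00153), and ACTG2, a smooth muscle actin, by 1.60 (SE 0.11, adjusted p = 0.000153). NTS stood at 20.2 FPKM in KhES-3 and 29.3 FPKM in 201B7 under DMSO, and at 82.4 and 108 FPKM under 1 µM thalidomide. The mitotic kinesin KIFC1 (1.85), the inward rectifier channel KCNJ2 (1.71), the LIM homeobox factor LHX8 (1.70) and the galectin CLC (1.65) rose too. So did the zinc finger protein BNC1 (1.59), the kinase CAMK2D (1.51) and the receptor CALCRL (1.51). ACTA1, skeletal muscle actin, fell by 1.51 on the log2 scale (SE 0.22, adjusted p = 0.00292). GAL, the neuropeptide galanin, fell by 1.48 (SE 0.12, adjusted p = 0.000261), and NPTX1, neuronal pentraxin, fell by 1.42 (SE 0.19, adjusted p = 0.00223). GAL went from 129 to 43.7 FPKM in KhES-3 and from 122 to 34.0 FPKM in 201B7 between DMSO and 1 µM thalidomide. NKAIN4 (-1.21), the troponin TNNC1 (-1.12), LINC00428 (-1.11) and the neuronal calcium sensor VSNL1 (-1.09) fell as well. PPP1R17 (-1.07), S100A14 (-1.05) and CKMT1B, a mitochondrial creatine kinase with a near-identical copy (-1.06), also fell. Over all 13358 genes, 747 rose and 737 fell in limma, 25 and 21 of them by over 2-fold. All 1484 had the same sign in 4 of 4 thalidomide libraries against the DMSO library of their line. The choice of genes favours this, since they were called on these same differences and both doses of a line share its DMSO library. The count was 127 without the KhES-3 DMSO library, 306 without the 201B7 DMSO library, 899 without the KhES-3 1 µM library and 849 without the 201B7 1 µM library. Of the 20 genes named, 14 kept their call whichever library was left out. KIFC1 and ACTA1 lost it without the 201B7 DMSO library (adjusted p = 0.103 and 0.0585), and KCNJ2 and NPTX1 without the KhES-3 DMSO library (adjusted p = 0.100 and 0.0556). CLC and S100A14 lost it without either DMSO library (adjusted p up to 0.240 and 0.102), and CLC with no filter (adjusted p = 0.0585). The count was 967 with no filter and 6 with no cell line term, which adds the line difference to the spread. KIFC1 lies at the edge of the major histocompatibility region, where values moved between libraries of the same line.

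**Figure D1:**
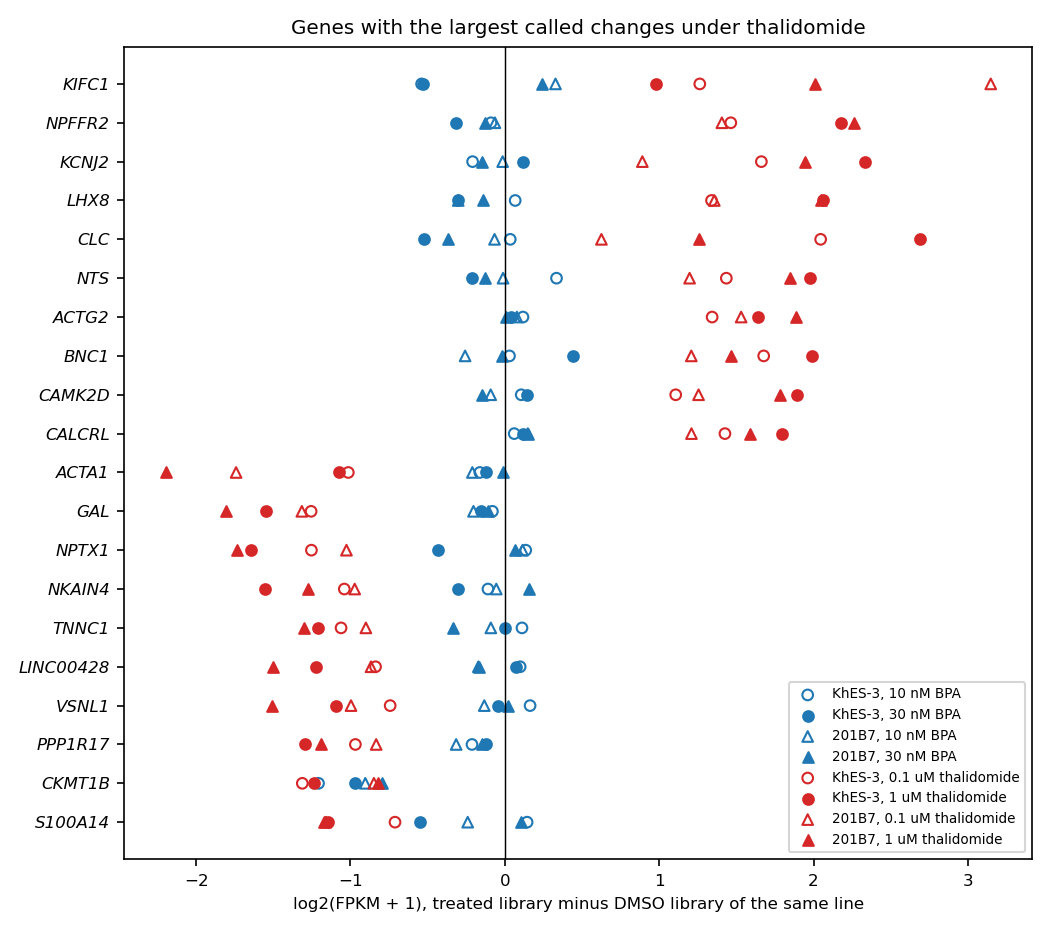
Each point is 1 treated library minus the DMSO library of its line on log2(FPKM + 1), for the 20 genes with the largest called changes under thalidomide; circles are KhES-3, triangles 201B7, open symbols the lower and filled symbols the higher dose. Red thalidomide points lie on one side of 0 in 4 of 4 libraries for each gene, which the choice of the genes on these same values favours.

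The list of direct targets and receptors held cereblon, its ligase partners, proteins reported as degraded through it under thalidomide or related compounds, and hormone receptors. Of 23 measured members, 2 rose under thalidomide and 0 fell, over all genes in limma and adjusted over the list alone. Over all 13358 genes, 747 rose and 737 fell. SALL4, a transcription factor degraded through cereblon under thalidomide, rose by 0.38 on the log2 scale (SE 0.057, adjusted p = 0.00328). It went from 64.1 to 89.8 FPKM in KhES-3 and from 60.5 to 82.1 FPKM in 201B7 at 1 µM. ZNF692, another such protein, rose by 0.55 (SE 0.12, adjusted p = 0.020). Cereblon itself, CRBN, differed by 0.11 (SE 0.076, adjusted p = 0.384), and the ligase member DDB1 by 0.032 (SE 0.033, adjusted p = 0.581). The calls of SALL4 and ZNF692 ended without either DMSO library, with an adjusted p of up to 0.0621 and 0.222, and that of ZNF692 with no filter (adjusted p = 0.0564). The list as a whole did not pass (camera adjusted p = 0.420).

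Among genes of primed pluripotency, 9 of 29 fell under thalidomide and 2 rose, or 13 and 4 adjusted over the list alone. ESRG, a long noncoding RNA of pluripotent cells, fell by 0.39 on the log2 scale (SE 0.057). The DNA methyltransferase DNMT3B fell by 0.46 (SE 0.088), the nodal co-receptor TDGF1 fell by 0.33 (SE 0.059), and the growth factor FGF2 fell by 0.36 (SE 0.084). DNMT3B stood at 363 and 351 FPKM under DMSO in KhES-3 and 201B7 and at 231 and 240 FPKM under 1 µM thalidomide. GAL is a member of the list too, and FOXD3 (-0.30) and TERT (-0.40) fell, while CD24 (0.15) rose. The list passed as lower (camera adjusted p = 0.00661), with adjusted p = 0.332 with an estimated correlation. ESRG lost its call without the KhES-3 DMSO library (adjusted p = 0.0556). DNMT3B, TDGF1, FGF2, FOXD3, TERT and CD24 lost theirs without either DMSO library (adjusted p up to 0.282). FGF2 lost it also without the 201B7 1 µM library (adjusted p = 0.0540). TERT lost it without the KhES-3 0.1 µM or either 1 µM library (adjusted p = 0.0512 to 0.0695), and CD24 without the 201B7 0.1 µM or either 1 µM library (adjusted p = 0.0564 to 0.0664). With no filter FGF2, TERT and CD24 were not called (adjusted p = 0.0625 to 0.0841), with no intensity trend CD24 (adjusted p = 0.0777), and with the length and GC trend removed TERT (adjusted p = 0.0574). Of 7 naive pluripotency genes 1 rose and 1 fell, also adjusted over the list alone. DPPA5, whose mean FPKM lay under 2, fell by 1.43 (SE 0.17, adjusted p = 0.00151), and the naive list did not pass (camera adjusted p = 0.512).

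Genes of G2 and mitosis were higher under thalidomide by small amounts. Of 26 genes 7 rose and 0 fell, or 11 and 0 adjusted over the list alone. The hyaluronan receptor HMMR rose by 0.24 on the log2 scale (SE 0.040, adjusted p = 0.00594), the mitotic kinase CDK1 by 0.23 (SE 0.046, adjusted p = 0.0115) and NUSAP1 by 0.19 (SE 0.035, adjusted p = 0.00772). CENPE (0.24), BUB1 (0.20), KIF23 (0.18) and CCNB2 (0.17) rose too. The list passed as higher (camera adjusted p = 8.52e-05), with adjusted p = 0.332 with an estimated correlation. Genes of S phase did not pass (1 rose and 1 fell of 26, also adjusted over the list alone, camera adjusted p = 0.531). Of 24 p53 targets, 4 rose and 0 fell, or 5 and 0 adjusted over the list alone. These were the polo-like kinase PLK2 (0.89, SE 0.19), the ribonucleotide reductase subunit RRM2B (0.31, SE 0.068), TP53INP1 (0.36, SE 0.088) and the cyclin CCNG1 (0.24, SE 0.047). The p53 list passed as higher (camera adjusted p = 0.0159), with adjusted p = 0.332 with an estimated correlation and adjusted p = 0.0520 under the filter at 5 FPKM. The calls of all 11 genes ended without either DMSO library (adjusted p up to 0.271), those of CENPE and TP53INP1 also without the 201B7 1 µM library (adjusted p = 0.0610 and 0.0677) and that of CENPE without the KhES-3 1 µM library (adjusted p = 0.0549). CENPE, BUB1 and KIF23 lost theirs with the length and GC trend removed (adjusted p = 0.169, 0.0529 and 0.0530), BUB1 with no intensity trend (adjusted p = 0.0568), and PLK2 and TP53INP1 with no filter (adjusted p = 0.0543 and 0.0628).

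Metallothioneins, which bind zinc and copper, were lower under thalidomide. Of 8 genes 3 fell and 0 rose, or 4 and 0 adjusted over the list alone. MT1X fell by 0.78 on the log2 scale (SE 0.14, adjusted p = 0.00788), MT1G fell by 0.57 (SE 0.15, adjusted p = 0.0333) and MT1H fell by 0.79 (SE 0.21, adjusted p = 0.0357). MT1X went from 1067 to 539 FPKM in KhES-3 and from 211 to 103 FPKM in 201B7 at 1 µM. The list passed as lower (camera adjusted p = 0.00735), with adjusted p = 0.405 with an estimated correlation. Its median difference from DMSO over both doses was -0.71 in KhES-3 and -0.051 in 201B7, and the difference between the lines was not tested for the list. The 3 calls ended without either DMSO library (adjusted p up to 0.368), and those of MT1G and MT1H also without either 1 µM library and without the 201B7 10 nM bisphenol A library (adjusted p = 0.0511 to 0.0799). MT1G and MT1H were not called either with the length and GC trend removed (adjusted p = 0.0732 and 0.0519), with no filter (adjusted p = 0.0881 and 0.0936) or with no intensity trend (adjusted p = 0.0628 and 0.0647).

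Of 76 cytosolic ribosomal protein genes, 2 fell under thalidomide and 0 rose, or 1 and 0 adjusted over the list alone. Over all 13358 genes, 737 fell and 747 rose. The list median was -0.074 on the log2 scale. The list passed as lower (camera adjusted p = 3.16e-08), with adjusted p = 0.565 with an estimated correlation. Of 70 respiratory chain genes 3 fell and 0 rose, or 1 and 0 adjusted over the list alone, among them the ATP synthase subunit ATP5D (-0.31, SE 0.041). That list passed as lower (camera adjusted p = 0.0286), with adjusted p = 0.692 with an estimated correlation and adjusted p = 0.177 under quantile normalization. Among 36 replication-dependent histone genes, whose close copies share sequence, 3 fell and 1 rose, also adjusted over the list alone. HIST1H2AG (-0.77, SE 0.16) and HIST2H4A (-0.71, SE 0.18) fell and HIST1H3H (0.88, SE 0.22) rose. The histone list passed as lower (camera adjusted p = 0.0216), with adjusted p = 0.565 with an estimated correlation and adjusted p = 0.0530 under quantile normalization. Its median difference from DMSO over both doses was -0.50 in KhES-3 and -0.028 in 201B7, and the difference between the lines was not tested for the list. Only 5 of the 18 listed trophoblast and amnion genes were tested. Of these, the keratin KRT7 (-0.77, SE 0.12) and the receptor subunit GABRP (-0.35, SE 0.091) fell, also adjusted over the list alone. The trophoblast list passed as lower (camera adjusted p = 0.0300), with adjusted p = 0.332 with an estimated correlation. The calls of the 6 genes named here each ended without the KhES-3 DMSO library (adjusted p up to 0.374). HIST1H2AG, HIST2H4A and GABRP lost theirs also without the 201B7 DMSO library (adjusted p up to 0.0980), and HIST2H4A, HIST1H3H and GABRP without the KhES-3 1 µM library (adjusted p up to 0.0620). HIST2H4A lost it without the KhES-3 0.1 µM or 201B7 1 µM library (adjusted p = 0.0592 and 0.0543), HIST1H3H without the 201B7 0.1 µM library (adjusted p = 0.0538), and GABRP without the 201B7 10 nM library (adjusted p = 0.0513). With no filter HIST2H4A, HIST1H3H and GABRP were not called (adjusted p = 0.0781, 0.0637 and 0.0731).

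Several genes of lists that did not pass also changed under thalidomide. Vimentin, VIM, rose by 1.15 on the log2 scale (SE 0.17, adjusted p = 0.00328), from 76.3 to 258 FPKM in KhES-3 and from 208 to 400 FPKM in 201B7 at 1 µM. The collagen COL5A2 rose by 1.05 (SE 0.18), while the collagen COL1A1 fell by 0.76 (SE 0.078, adjusted p = 0.000802). Their list of fibroblast and mesenchyme genes had 3 higher and 3 lower of 16, or 5 and 4 adjusted over the list alone, with a median of -0.0049, a mean of 0.13 and a camera test that pointed lower (adjusted p = 0.752). Of 11 notch targets 4 fell and 1 rose, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.0519). HEY2 (-0.80, SE 0.15) and LFNG (-0.70, SE 0.096) were among those that fell. The endothelial receptor KDR fell by 0.85 (SE 0.15). Among oestrogen response genes 5 of 17 fell and 1 rose, or 7 and 2 adjusted over the list alone, without the list passing (camera adjusted p = 0.0747). The amino acid transporter SLC7A5 (-0.72, SE 0.15) and the transcription factor MYC (-0.46, SE 0.083) were among those that fell. COL1A1 kept its call whichever library was left out. VIM (adjusted p = 0.0866), COL5A2 (0.133), KDR (0.133), HEY2 (0.162) and LFNG (0.0574) lost theirs without the KhES-3 DMSO library, and SLC7A5 and MYC without either DMSO library (adjusted p up to 0.160 and 0.0949).

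The dose comparison asked whether the changes grew with dose. NPFFR2, the receptor named first, went from 2.92 FPKM under DMSO to 9.82 and 16.7 FPKM at 0.1 and 1 µM thalidomide in KhES-3, and from 4.84 to 14.5 and 27.03 FPKM in 201B7. At 0.1 µM, 194 genes rose and 223 fell, and at 1 µM 783 rose and 761 fell. At both doses 185 genes were called higher and 213 lower. Independent lists of these sizes would share 11.4 and 12.7, but these lists are not independent. In 20 sets of data simulated without changes on shared DMSO libraries, a mean of 0.1 genes was called alike at both doses. These sets held no changed genes and no shift of a whole library, so a low count was fixed in advance. It does not tell how much of the overlap comes from the shared DMSO libraries. Both doses share the DMSO libraries, and their log2 changes correlated across genes at 0.800, against 0.504 in simulated data that shared only these libraries. Of the 1484 genes called over both doses, 970 (65.4%) differed more at 1 than at 0.1 µM in both lines and 120 (8.09%) less in both. Genes that varied independently would give 25% each. With 1 library per line and dose, a shift of a single library moves many genes together, so these shares do not test the dose. Their median size was 0.29 at the lower and 0.38 at the higher dose on the log2 scale. Tested gene by gene in limma, 0 genes differed between the doses, with 1123 at an unadjusted p under 0.05 where 668 are expected. The smallest adjusted p was 0.0510, for NPFFR2. That count was 1 without the KhES-3 30 nM bisphenol A library and 2 without the KhES-3 0.1 µM library. Under the filter at 5 FPKM 4 genes were called, NPFFR2, EFR3A, SGK1 and TSPAN12, the last 3 named after their values were seen. The count at 0.1 µM was 33 without the KhES-3 DMSO, 85 without the 201B7 DMSO, and 48 and 92 without the 0.1 µM libraries of KhES-3 and 201B7. The count at 1 µM was 430 without the KhES-3 DMSO, 603 without the 201B7 DMSO, and 551 and 854 without the 1 µM libraries of KhES-3 and 201B7.

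The comparison of bisphenol A with DMSO asked which genes changed after exposure to a plasticiser with weak oestrogen activity. CKMT1B, a mitochondrial creatine kinase, fell by 0.97 on the log2 scale (SE 0.098, adjusted p = 0.0138). It went from 15.8 FPKM under DMSO to 6.27 and 7.55 FPKM at 10 and 30 nM in KhES-3 and from 11.6 to 5.72 and 6.24 FPKM in 201B7. CKMT1B was the only gene called of 13358 tested in limma (0 higher and 1 lower, 666 at an unadjusted p under 0.05 where 668 are expected). Under thalidomide it fell by 1.06. Other genes had the same sign in both lines and at both doses and did not pass. Above 0 were HIST1H4K (1.36, SE 0.21, adjusted p = 0.315), FSBP (1.09, SE 0.22), IQCG (0.50, SE 0.093), LINC00847 (0.39, SE 0.078) and TRAPPC2L (0.25, SE 0.052). Below 0 were TMEM160 (-0.36, SE 0.075), S100A4 (-0.26, SE 0.059), ATP5D (-0.19, SE 0.041) and H2AFX (-0.17, SE 0.040), and apart from HIST1H4K these genes had an adjusted p of 0.939. For 12841 genes (96.1%) the 95% interval of the change lay within 1.5-fold, taken on FPKM + 1. For genes near 1 FPKM this allows a larger fold of the FPKM itself. CKMT1B has a near-identical copy, CKMT1A, and its call ended without the KhES-3 DMSO library (adjusted p = 0.621) and without the 201B7 10 nM or 30 nM library (adjusted p = 0.0885 and 0.0728). It ended also with no filter (adjusted p = 0.195), with no intensity trend (adjusted p = 0.0732) and with no cell line term (adjusted p = 0.368). The count was 2 without the KhES-3 10 nM, KhES-3 30 nM, KhES-3 1 µM thalidomide or 201B7 DMSO library, and HIST1H4K was called without the KhES-3 30 nM library (adjusted p = 0.0231).

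Among the gene lists, cytosolic ribosomal protein genes were lower under bisphenol A, with a median of -0.032 (-0.056 in KhES-3 and -0.0084 in 201B7, a difference that was not tested). Of 76 members 0 were called in limma, over all genes or adjusted over the list alone. The list passed (camera adjusted p = 0.000142), with adjusted p = 0.681 with an estimated correlation and adjusted p = 0.408 under quantile normalization. Nodal and activin targets did not pass (camera adjusted p = 0.0649), with a median of -0.19 in KhES-3 and -0.12 in 201B7. Of 11 members 0 were called in limma, and 1 was lower adjusted over the list alone, CER1, which differed by -0.58 (SE 0.14, adjusted p = 0.939 over all genes). Of 17 oestrogen response genes 0 were called, also adjusted over the list alone, with a median of -0.041 (camera adjusted p = 0.259). The oestrogen receptor gene ESR1 was listed at 0 to 0.0445 FPKM in the 10 libraries. Of the 23 direct targets and receptors 0 were called, also adjusted over the list alone. The related receptor ESRRA differed by -0.090 (SE 0.052, adjusted p = 0.939). By dose, limma called 0 genes at 10 nM (715 at an unadjusted p under 0.05, smallest adjusted p = 0.0767) and 0 at 30 nM (678, smallest adjusted p = 0.309). Between the doses it called 0 genes (633 at an unadjusted p under 0.05, smallest adjusted p = 0.727). Without the KhES-3 10 nM library the count at 10 nM was 2. At 30 nM it was 4 without the KhES-3 30 nM library and 1 without the 0.1 µM thalidomide library of either line. Between the doses it was 3 without the KhES-3 30 nM library, 2 without the 10 nM library of either line and 1 without the 0.1 µM thalidomide library of either line. Under the filter at 5 FPKM, CKMT1B was called at 10 nM (-1.06, adjusted p = 0.0459).

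Across genes, the changes of both lines were compared to see what they share. The changes under thalidomide in KhES-3 and in 201B7, each against its own DMSO library, correlated across genes at 0.39 for the 0.1 µM and 0.59 for the 1 µM libraries. The changes under bisphenol A correlated at 0.0075 to 0.077. Genes are not independent replicates, so no p is given, and 16 such pairs of libraries were computed.

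**Figure D2:**
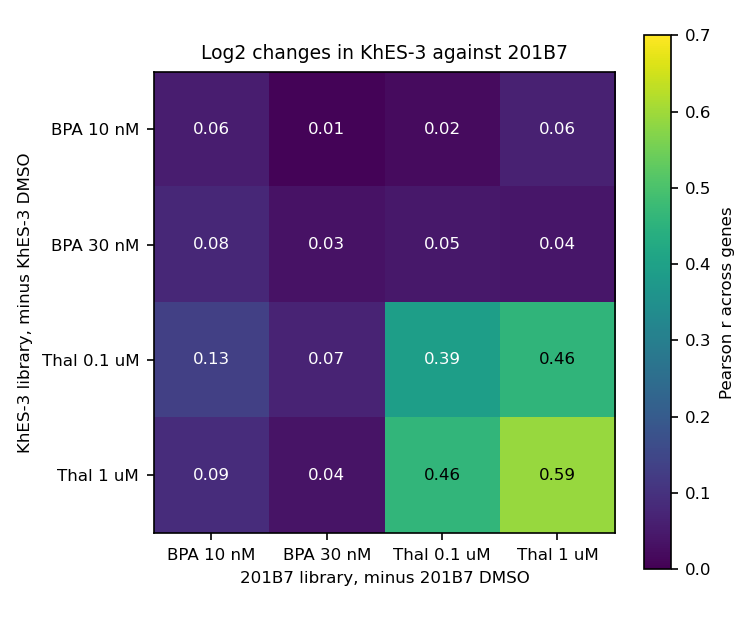
Pearson correlation across 13358 genes of the log2 change in a KhES-3 library (vertical axis) and in a 201B7 library (horizontal axis), each against the DMSO library of its line. The 4 pairs of thalidomide libraries lie between 0.39 and 0.59 and the other pairs between 0.0075 and 0.13.

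The comparison of bisphenol A with thalidomide asked how the compounds differ. No DMSO library enters the difference itself, while the spread comes from all 10 libraries. Higher under bisphenol A were neuronal pentraxin NPTX1 (1.39, SE 0.16), skeletal actin ACTA1 (1.38, SE 0.18) and galanin GAL (1.34, SE 0.096). NKAIN4 (1.13), VSNL1 (1.09), LINC00428 (1.07), TNNC1 (1.04), the metallothionein MT1H (1.03), LHFP (0.95) and the cartilage matrix gene UCMA (0.91) were higher too. Lower were NPFFR2 (-1.98, SE 0.18), KIFC1 (-1.98, SE 0.26), CLC (-1.89, SE 0.30), LHX8 (-1.87, SE 0.18) and LGALS14, a galectin of the CLC family (-1.83, SE 0.49). KCNJ2 (-1.77), NTS (-1.62), ACTG2 (-1.54) and BNC1 (-1.54) were lower too. Of nodal and activin targets 3 were higher and 5 lower of 11, also adjusted over the list alone (camera adjusted p = 0.420). The antagonists LEFTY2 (-1.13, SE 0.18), CER1 (-0.996, SE 0.11) and LEFTY1 (-0.85, SE 0.22) and the ligand GDF3 (-0.72, SE 0.12) were among the lower. In limma, 983 genes were higher under bisphenol A and 1037 lower, 10 and 32 of them by over 2-fold. The count was 1206 without the KhES-3 1 µM and 1310 without the 201B7 1 µM library. LGALS14 lost its call without any 1 of the treated KhES-3 libraries (adjusted p up to 0.0761), with no filter (adjusted p = 0.0817) and with no intensity trend (adjusted p = 0.0543). LEFTY1 lost it without the KhES-3 1 µM, 201B7 1 µM or 201B7 10 nM library (adjusted p up to 0.0746) and with no filter (adjusted p = 0.0711). SERF1B, a gene with a near-identical copy, differed by -3.51 (SE 0.90) with values of 0.478 to 72.2 FPKM. It lost its call without any 1 of the treated 201B7 libraries (adjusted p up to 0.0764) and with no filter (adjusted p = 0.0745).

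Metallothioneins were higher under bisphenol A than under thalidomide, with 5 higher and 0 lower of 8, or 6 and 0 adjusted over the list alone. MT1X (0.89, SE 0.12), MT1G (0.76, SE 0.12) and MT1F (0.50, SE 0.11) were among them, and the list passed (camera adjusted p = 0.000563), with adjusted p = 0.401 with an estimated correlation. Primed pluripotency genes were higher, with 10 higher and 5 lower of 29, or 12 and 5 adjusted over the list alone. TDGF1 (0.40), FGF2 (0.48) and DNMT3B (0.43) were higher, while LEFTY2 (-1.13), LEFTY1 (-0.85) and GDF3 (-0.72), also members of this list, were among the 5 lower. The list median was 0.099 and its mean 0.055. SALL4, of the list of direct targets, was lower (-0.39, SE 0.047, adjusted p = 0.000701). The primed list passed (camera adjusted p = 0.0354), with adjusted p = 0.401 with an estimated correlation and adjusted p = 0.0556 under quantile normalization. Genes of G2 and mitosis were lower, NUSAP1 (-0.17) and PLK1 (-0.17) among them, with 0 higher and 7 lower of 26, or 1 and 7 adjusted over the list alone. The list passed (camera adjusted p = 0.000812), with adjusted p = 0.401 with an estimated correlation. Of p53 targets 0 were higher and 5 lower of 24, also adjusted over the list alone, PLK2 (-1.02, SE 0.16) among them. The p53 list passed (camera adjusted p = 0.0354), with adjusted p = 0.401 with an estimated correlation and adjusted p = 0.0583 under the filter at 5 FPKM. Imprinted genes were lower, with 1 higher and 5 lower of 22, or 1 and 9 adjusted over the list alone. GRB10 (-0.40), CDKN1C (-0.42), PEG10 (-0.24), NNAT (-0.26) and GNAS (-0.16) were lower and MEG3 (0.28) was higher. The imprinted list passed (camera adjusted p = 0.0457), with adjusted p = 0.401 with an estimated correlation.

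Ribosomal protein genes were higher under bisphenol A than under thalidomide, with 3 higher and 0 lower of 76, or 2 and 0 adjusted over the list alone. That list passed (camera adjusted p = 0.000799), with adjusted p = 0.682 with an estimated correlation and adjusted p = 0.101 under quantile normalization. Histones were higher, with 4 higher and 0 lower of 36, or 3 and 0 adjusted over the list alone, HIST1H2AC (0.90, SE 0.20) among them. The histone list passed (camera adjusted p = 0.00508), with adjusted p = 0.401 with an estimated correlation and adjusted p = 0.0583 under the filter at 5 FPKM. Trophoblast and amnion genes were higher, with 2 higher and 0 lower of the 5 tested out of 18 listed, also adjusted over the list alone. Their list passed (camera adjusted p = 0.0460), with adjusted p = 0.401 with an estimated correlation, 0.0556 under quantile normalization and 0.0539 with a pseudocount of 0.1.

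The comparison of 201B7 with KhES-3 asked how these lines, 1 of each kind, differ, and it does not compare iPSC with ESC in general. Line means are given with the SD over n = 5 libraries of all treatments. The serotonin receptor HTR7 stood at 1.51 ± 0.37 FPKM in KhES-3 and 23.0 ± 1.52 FPKM in 201B7. The reductase DHRS2 stood at 0.829 ± 0.33 and 14.3 ± 2.43 FPKM, and the cytidine deaminase APOBEC3B at 1.64 ± 0.19 and 10.5 ± 2.03 FPKM. ZNF558, CCDC144NL-AS1, LOC284581, PCAT7, CD52 and RPS14P3 were also higher in 201B7, by 2.07 to 2.86 on the log2 scale. SERF1B, which has a near-identical copy, was higher (2.34, SE 0.67, adjusted p = 0.0132), but not without the 201B7 DMSO library (adjusted p = 0.0501) or with no treatment term (adjusted p = 0.118). Lower in 201B7 were the protease CTSF (16.6 ± 1.24 and 0.0852 ± 0.050 FPKM), the transcription factor MEF2B (22.1 ± 4.64 and 0.825 ± 0.36 FPKM) and the zinc finger gene ZNF208 (24.98 ± 1.78 and 0.00107 ± 0.0024 FPKM). The zinc finger genes ZNF676, ZNF98 and ZNF729 were listed at 0 in 5 of 5 libraries of 201B7 and at 19.8, 17.0 and 11.2 FPKM on average in KhES-3. The galectins CLC (-4.69, SE 0.24) and LGALS14 (-3.93, SE 0.45) were lower too. In limma 4294 genes were higher and 4151 lower, 151 and 252 by over 2-fold. Line, experiment series and the difference in relative depth between the lines run together in this design.

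Most genes of the integrated stress response, and metallothioneins, were lower in 201B7. DDIT3, the transcription factor CHOP, stood at 57.0 ± 4.55 FPKM in KhES-3 and 2.90 ± 0.62 FPKM in 201B7. CHAC1, which degrades glutathione, stood at 192 ± 5.14 and 20.2 ± 3.59 FPKM, and ATF3 at 54.1 ± 1.30 and 10.8 ± 1.15 FPKM. DDIT4, an inhibitor of mTORC1, stood at 376 ± 28.6 and 31.6 ± 3.81 FPKM. Of 27 genes of the integrated stress and unfolded protein response, 17 were lower and 7 higher, or 17 and 8 adjusted over the list alone. The list passed (camera adjusted p = 0.000747), with adjusted p = 0.551 with an estimated correlation. All 8 metallothioneins tested were lower in 201B7, also adjusted over the list alone, MT2A at 344 ± 54.5 FPKM in KhES-3 and 59.7 ± 9.67 FPKM in 201B7. The metallothionein list passed (camera adjusted p = 2.94e-06), with adjusted p = 0.187 with an estimated correlation. Of 18 immediate early genes 13 were lower and 1 higher, or 14 and 1 adjusted over the list alone, with MYC (-1.13, SE 0.053) and SPRY4 (-1.20, SE 0.042). The immediate early list passed (camera adjusted p = 0.000467), with adjusted p = 0.187 with an estimated correlation. Of the 8 BMP targets tested, out of 18 listed, 5 were lower and 0 higher, also adjusted over the list alone. Among them was ID1 at 171 ± 20.2 and 79.9 ± 6.67 FPKM. The BMP list passed (camera adjusted p = 0.0213), with adjusted p = 0.299 with an estimated correlation.

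Genes of the heat shock response were higher in 201B7, the chaperone HSPA8 at 325 ± 47.6 FPKM in KhES-3 and 1050 ± 12.3 FPKM in 201B7. Of 14 genes 13 were higher and 0 lower, also adjusted over the list alone, and the list passed (camera adjusted p = 9.10e-06), with adjusted p = 0.551 with an estimated correlation. Of 25 genes of cholesterol biosynthesis 20 were higher and 2 lower, also adjusted over the list alone. INSIG1, a regulator of the pathway, stood at 6.42 ± 1.10 and 24.0 ± 0.56 FPKM and the enzyme HMGCS1 at 34.8 ± 6.46 and 85.1 ± 3.84 FPKM. The cholesterol list passed (camera adjusted p = 9.10e-06), with adjusted p = 0.551 with an estimated correlation. Only 8 of the 26 listed neuroectoderm genes were tested. Of these 7 were higher and 0 lower, also adjusted over the list alone, including TUBB3 (0.98, SE 0.088), SOX3 (0.82, SE 0.049) and NES (0.77, SE 0.026). The neuroectoderm list passed (camera adjusted p = 0.00103), with adjusted p = 0.187 with an estimated correlation. Genes of S phase were higher, with 13 higher and 5 lower of 26, also adjusted over the list alone, and PCNA stood at 147 ± 7.27 and 247.0 ± 9.53 FPKM. The S phase list passed (camera adjusted p = 0.0234), with adjusted p = 0.669 with an estimated correlation and 0.0900 under quantile normalization. Genes of G2 and mitosis were higher, with 16 higher and 5 lower of 26, also adjusted over the list alone, while the spindle factor TPX2 was lower (-0.61, SE 0.028). The G2 list passed (camera adjusted p = 0.0234), with adjusted p = 0.551 with an estimated correlation and 0.0710 under quantile normalization. Of 24 p53 targets 15 were higher and 5 lower, also adjusted over the list alone, CDKN1A higher (1.07, SE 0.058) and SESN2 lower (-1.98, SE 0.037). The p53 list passed as higher (camera adjusted p = 0.0367), with adjusted p = 0.594 with an estimated correlation and 0.176 under the filter at 5 FPKM.

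**Figure D3:**
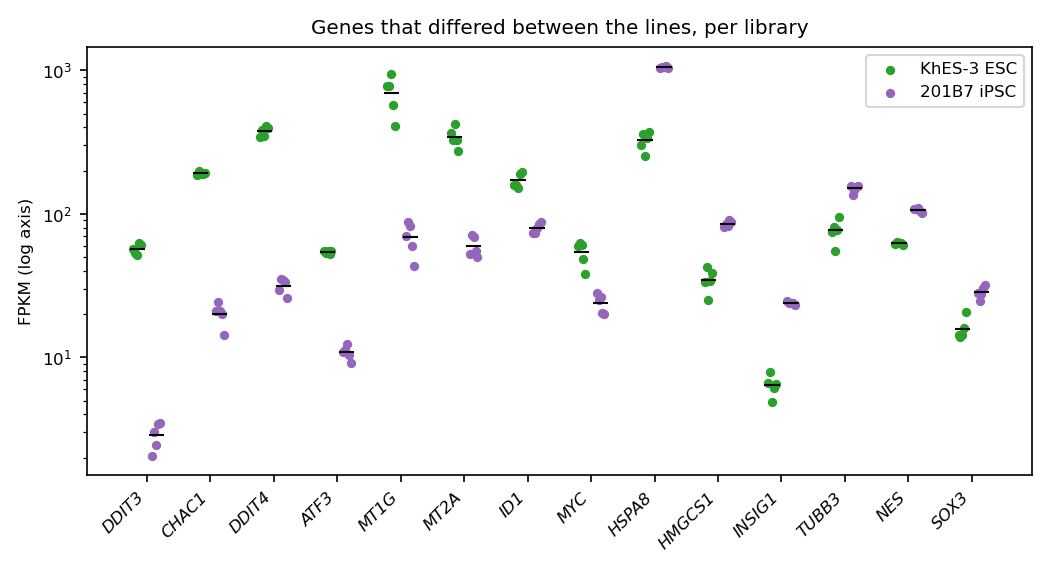
FPKM on a log axis of 14 genes, chosen for the plot after their values were seen; each point is 1 library, 5 per line over all treatments, and the bar is the mean. DDIT3, CHAC1, DDIT4 and ATF3 lie lower in 201B7, and HSPA8, HMGCS1 and INSIG1 higher.

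Genes known to vary among human pluripotent lines were lower in 201B7. FAM19A5 was listed at 0 in 5 of 5 libraries of 201B7 and stood at 6.68 ± 0.38 FPKM in KhES-3, and ZNF560 stood at 11.8 ± 0.96 FPKM in KhES-3 and 0.716 ± 0.097 FPKM in 201B7. The imprinted gene NNAT was lower (-1.84, SE 0.040) and the catalase gene CAT higher (0.75, SE 0.068). Of 21 genes 4 were higher and 12 lower, also adjusted over the list alone, and the list passed (camera adjusted p = 0.00296), with adjusted p = 0.187 with an estimated correlation. Ribosomal protein genes were higher, with 38 higher and 6 lower of 76, or 38 and 5 adjusted over the list alone, RPS26 (1.34) and RPL9 (1.03), which have close copies, among them. The ribosomal list passed (camera adjusted p = 0.00324), with adjusted p = 0.781 with an estimated correlation, and its direction turned to lower under quantile normalization (adjusted p = 0.102). Respiratory chain genes were higher, with 32 higher and 10 lower of 70, also adjusted over the list alone. The respiratory list passed (camera adjusted p = 0.0234), with adjusted p = 0.781 with an estimated correlation and 0.725 under quantile normalization. Histones were lower, with 2 higher and 13 lower of 36, or 2 and 12 adjusted over the list alone, HIST1H2AC (-3.18, SE 0.16) among them. Over all 13358 genes, 4294 were higher and 4151 lower between the lines. The histone list passed (camera adjusted p = 0.0367), with adjusted p = 0.633 with an estimated correlation, 0.0730 under quantile normalization and 0.0568 with a pseudocount of 0.1. Primed pluripotency genes did not pass as a list, with 6 higher and 14 lower of 29, also adjusted over the list alone (camera adjusted p = 0.235). NANOG stood at 57.7 ± 2.56 FPKM in KhES-3 and 34.9 ± 2.45 FPKM in 201B7. POU5F1 was listed at 74.4 ± 2.79 and 7.88 ± 0.80 FPKM, but it has copies and lies in the major histocompatibility region, where values differed between the lines more often than those of matched genes.

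The line difference in the response was tested with the interaction model. Among the genes of smallest p were RPPH1 and HIATL2 for bisphenol A and ANXA3 and TXNIP, a glucose-responsive arrestin, for thalidomide. TXNIP went from 96.7 to 111 FPKM in KhES-3 and from 11.95 to 25.4 FPKM in 201B7 at 1 µM. Limma called 0 genes for bisphenol A (424 at an unadjusted p under 0.05, smallest adjusted p = 0.336) and 0 for thalidomide (600, smallest adjusted p = 0.414), where 668 are expected by chance. Over the 20 genes named for thalidomide, the smallest adjusted p of the difference was 0.0653, for ACTA1. ACTA1 stood at 12.7 FPKM under DMSO and 5.51 FPKM under 1 µM thalidomide in KhES-3 and at 42.4 and 8.46 FPKM in 201B7. For bisphenol A, 1 gene was called without the KhES-3 0.1 µM or the KhES-3 1 µM thalidomide library, and 2 without the 201B7 10 nM or 30 nM library. For thalidomide, 2 genes were called without the KhES-3 1 µM library and 1 without the 201B7 10 nM or 30 nM library. With no filter 28 and 26 genes were called. The 95% interval of the line difference lay within 1.5-fold, taken on FPKM + 1, for 72.6% of the genes for bisphenol A and 70.8% for thalidomide.

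Within each line, values at both doses were set against DMSO with no test. In KhES-3 the galectin CLC went from 39.5 FPKM under DMSO to 166 and 260 FPKM at 0.1 and 1 µM thalidomide, and LGALS14 from 7.07 to 43.7 and 104 FPKM. In 201B7, CLC went from 1.31 to 2.56 and 4.52 FPKM, and LGALS14 was listed at 0, 0.43 and 0.78 FPKM. The line difference in the response of CLC did not pass (adjusted p = 0.108 over the 20 genes named). By over 2-fold at both doses, 22 genes were higher and 16 lower under thalidomide in KhES-3, and 11 and 10 in 201B7. Under bisphenol A there were 4 and 7 in KhES-3 and 2 and 3 in 201B7. GAL, NPTX1 and DPPA5 in KhES-3 and NPFFR2, LHX8, ACTG2, ACTA1 and GAL in 201B7 were among the genes that differed most under thalidomide. Some genes found this way have close copies or lie in the major histocompatibility region. HNRNPA1P10 stood at 9.80 FPKM under DMSO, 0 under both bisphenol A doses and 51.7 and 52.0 FPKM under thalidomide in KhES-3. In 201B7 it stood at 0.124 FPKM under DMSO, 27.5 and 103 FPKM under bisphenol A, and 32.05 and 0 FPKM under thalidomide. C6orf48 stood at 19.3 FPKM under DMSO, 0.669 and 0.803 FPKM under bisphenol A, and 1.86 and 18.2 FPKM under thalidomide in KhES-3. In 201B7 it stood at 7.74 FPKM under DMSO, 1.60 and 1.19 FPKM under bisphenol A, and 0.862 and 1.70 FPKM under thalidomide. The metallothioneins had a median difference from DMSO of 0.29 under bisphenol A in 201B7 and 0.014 in KhES-3, against the single DMSO library of each line.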

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

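No result met the rules for a closer look: each line and treatment had 1 library, so no group could be searched for a library far from the others, and the test of the line difference passed for none of the 10 genes named for bisphenol A or the 20 named for thalidomide. Of the tests below, the counts over all splits were chosen before the results were seen; those over splits within lines or treatments, on CKMT1B, on POU5F1, on transcript length and GC content and on the DMSO libraries were chosen only after.

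Chance as the source of the count between bisphenol A and thalidomide was tested on the 35 splits of the 8 treated libraries into 4 and 4. Of these, 1, the real one, gave as many called genes (2020), and the highest of the other splits gave 1. For the lines, 1 of 100 splits drawn from 126, the real one, gave as many (8445), and the highest of the others gave 0. A split that mixes the lines adds their difference to the spread, so a low count there was largely fixed in advance. Over all splits both shares lay under 0.05, but these splits do not keep the lines or treatments balanced, so chance is not excluded. The 18 splits with 2 libraries of each line per group (real 2020, highest other 1) and the 16 with 1 library of each treatment per group (real 8445, highest other 0) are too few for a share under 0.05. The comparisons with DMSO hold 2 control libraries, too few for such a count.

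CKMT1B was lower under bisphenol A, and lower alike under thalidomide. Reads divided differently between it and its copy CKMT1A are argued against, since the summed FPKM of both fell as well (-0.82 on the log2 scale, SE 0.087). The difference between the compounds was 0.085 (SE 0.080, 95% interval -0.09 to 0.26). DMSO libraries that stand apart from every treated library, for whatever reason, and a like response to both compounds therefore cannot be told apart. Each line has a single DMSO library, and whether treated cells also received DMSO was not stated. A biological response stays open and untested.

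POU5F1, a core factor of pluripotency, was listed at 74.4 ± 2.79 FPKM in KhES-3 and 7.88 ± 0.80 FPKM in 201B7 (SD, n = 5 libraries). An assignment of its reads to the copies POU5F1B, POU5F1P3 and POU5F1P4 in 201B7 would raise their summed FPKM if the total were alike in both lines. The sum was not higher there (522 ± 24.3 in KhES-3 and 494 ± 15.8 in 201B7, a difference of -28.8), while POU5F1 lacked 66.5 FPKM. In both lines the copies held more FPKM than POU5F1 itself. With a lower total in 201B7 the sum could stay flat under such an assignment, so the test does not decide. A candidate explanation is line-specific alignment in the major histocompatibility region, where 13 of 45 other genes (28.9%) differed by over 2-fold between the lines, against a median of 4.44% in random lists matched on expression, and where the median residual SD was 0.184 against 0.0773 elsewhere. This remains a hypothesis, and a difference between the lines in POU5F1 itself stays open and untested.

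The thalidomide response may depend on a trend of the values with transcript length and GC content. Changes against DMSO under thalidomide had Spearman correlations of 0.134 to 0.205 with length and -0.310 to -0.151 with GC content. Under bisphenol A these were 0.0107 to 0.212 and -0.282 to -0.0736, so the trend was not particular to thalidomide. All libraries of a line share its DMSO library here, so the source of the trend cannot be told. With the trend removed, 1082 of 1442 matched genes stayed called in the same direction, 75.03% (SE 1.14). That SE takes genes as independent, which they are not, so it may be too small. The share lies on the bound set for the test and does not decide. A test on the size of the changes was added after that share had been seen: a median of 92.1% of the log2 change was left (quartiles 82.3% and 103%), which argues against the trend as the source of most of the change. The 360 genes that lost their call had a median change of 0.24 before and 0.17 after, with an SE of 0.062 and 0.060. Their median SE did not grow, while a smaller change is in part fixed by choosing genes that lost their call. DMSO libraries that stand apart from every treated library are argued against as the source of most of the response. The 1484 called genes showed a median of 17.1% of their log2 change under bisphenol A (quartiles 2.08% and 34.0%). Of them, 1157 were also called, in the matching direction, between bisphenol A and thalidomide, where no DMSO library enters the difference. The changes under both compounds had a covariance of 0.0105 across genes, against 0.00566 to 0.00909 in data simulated to share only the DMSO libraries. For this shared part, DMSO libraries that stand apart, for whatever reason, and a like response to both compounds cannot be told apart. A biological response to thalidomide stays open as a hypothesis, while the size of single changes still depends on 1 DMSO library per line.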

How the results depend on the processing

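Removing the length and GC trend and leaving out the major histocompatibility region were chosen only after the data were seen. No count and no named gene reversed, while the list of ribosomal protein genes turned from higher to lower in 201B7 under quantile normalization (adjusted p = 0.102). The 12 comparisons and the list counts kept within 1.5 times their count except as follows, where the cause was not tested unless named. With no filter, and so 20336 genes tested, the count was 0 for bisphenol A, 967 for thalidomide, 101 for 0.1 µM thalidomide, and 28 and 26 for the line difference in the response to bisphenol A and thalidomide. With no intensity trend it was 0 for bisphenol A and 270 for 0.1 µM thalidomide. Without the cell line term, which adds the line difference to the spread, it was 0 for bisphenol A, 6 for thalidomide, 93 for bisphenol A against thalidomide, 0 for 0.1 µM and 21 for 1 µM thalidomide. Under the filter at 5 FPKM it was 1 for 10 nM bisphenol A and 4 for 1 against 0.1 µM thalidomide; the latter was 1 with the length and GC trend removed and 1 without the major histocompatibility region. With an estimated correlation, 0 lists were called in each of the 4 comparisons tested. Under quantile normalization 0 lists were called for bisphenol A and 5 for bisphenol A against thalidomide, and under the filter at 5 FPKM 5 for the latter.

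Leaving out each library in turn gave 0 to 2 genes for bisphenol A, 127 to 1605 for thalidomide, 1206 to 1957 for bisphenol A against thalidomide, 0 to 2 for 10 nM and 0 to 4 for 30 nM bisphenol A, 33 to 458 for 0.1 µM and 430 to 1725 for 1 µM thalidomide, 0 to 3 between the bisphenol A doses, 0 to 2 between the thalidomide doses, 7707 to 8025 between the lines, and 0 to 2 for each line difference in response, which could not be fitted without a DMSO library. Of 192 values of named genes, 1355 of 1509 alternatives kept direction and call and 154 lost the call; of 1920 fits without 1 library, 1736 kept both, 183 lost the call and 1 gained it. The depth behind these values is unknown, since counts were not used here.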

Other observations

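The group below was chosen after its values were seen, and no test was planned for it. The zinc finger genes ZNF208, ZNF676, ZNF98 and ZNF729, lower in 201B7, are neighbours on chromosome 19. Of 18 zinc finger genes tested there, 13 were lower in 201B7 and 1, ZNF43, was higher, with a median log2 difference of -0.74. These include the 4 genes that prompted the choice; of the other 14, 9 were lower and 1 higher, with a median of -0.49. Of 468 other ZNF genes 266 were lower and 65 higher, with a median of -0.23. ZNF257 and ZNF492 were also listed at 0 in 5 of 5 libraries of 201B7, and stood at 3.43 ± 0.11 and 8.95 ± 1.27 FPKM in KhES-3 (SD, n = 5 libraries). ZNF91 and ZNF738, in the same group, differed by 0.11 (SE 0.047) and 0.040 (SE 0.046) and did not pass.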
